A study of Mus musculus with 2 samples.

How the data were processed

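DNase-seq libraries from the adrenal gland of male adult B6CASTF1/J mice were used, 1 library for each of biological replicates 1 and 2, with technical replicate number 1 in both, per the labels. The labels give the libraries separate tissue samples and 1 donor entry, so they do not say whether these came from separate animals, and p-values and spreads then measure only these samples and libraries. Reads, alignments and signal tracks were not used here.

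Peaks, footprints and false discovery rates were made by the authors for each library separately from a filtered alignment to mm10, per the file index text. The aligner, peak caller, footprint caller and their versions are not given in the sources used here. Each library had 2 deposited peak lists, and the longer was used throughout, with the shorter as an alternative. Every peak of the longer list held a position at an FDR of 0.05 or less in the deposited FDR file of its library, and every peak of the shorter list held one at 0.001 or less. The authors' height of each peak, a signal normalised for depth, came in whole multiples of 1 step per library, and 100% of heights lay within 0.05 of a whole number of steps. Dividing by the step gave a number of steps per height, with a median of 135 in replicate 1 and 100 in replicate 2. These are called cuts here on the assumption that 1 step is 1 cut. The depths derived from the steps hold only if the authors scaled heights to CPM, which the sources used here do not say. Peak widths had a median of 180 bp, and the lists covered 19.5 and 23.5 Mb. The summit column of the deposited peak lists held 75 in every row, so peak centres were used. The score in the deposited footprint lists was 0.01 in every row and was used for nothing. The false discovery rate (a q-value) in the files deposited by the authors was given per stretch of positions and listed only under 0.05, so the share of listed positions is given as a percent of the genome in place of the planned percent of tested positions.

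Coordinates are 1-based on GRCm38, the assembly that mm10 names, with the reference sequence and the GENCODE vM21 annotation of the same build. Sequences and motif matches are those of this reference. How the alleles of the mice used differ from it, and whether that affected alignment or peaks, was not examined. Chromosomes 1 to 19, X and Y were used. Genes were 21805 protein-coding genes with 54250 starts of protein-coding transcripts, after 48 records whose symbols named more than 1 gene were left out. A promoter was within 1 kb of such a start, and other peaks were placed in exons, introns or intergenic sequence of protein-coding genes by their centre. A peak was shared if it overlapped a peak of the other library by at least 1 bp (bedtools 2.31.1), and overlapping peaks of both libraries were merged into regions. Random overlap came from 100 placements of the same widths on the same chromosome from 3 Mb on, and, for footprints, from 100 placements inside the peaks that held them. Random positions numbered 200000. Shares of single libraries carry exact Clopper-Pearson 95% intervals, which cover counting error only. Heights were compared on the log2 scale without a pseudocount, since every listed height was above 0. An absent peak may be a withheld or filtered one, so it is described as not listed.

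There were 20 gene lists with 262 symbols, of which 260 matched the annotation. Bmal1 and Amy2b had no match and were left out. Bmal1 is another name of Arntl, which was on the list. The lists covered steroidogenesis, zonation and capsule signalling, cholesterol synthesis and uptake, chromaffin cells, macrophages, lymphocytes, endothelium, fibroblasts, Schwann cells, adipocytes, erythroid cells, stress and immediate early genes, clock genes, housekeeping genes, and controls for liver, kidney, muscle, forebrain, testis and pancreas. A gene was open where a merged region with a peak in both libraries lay within 1 kb of any of its starts. A region near starts of more than 1 gene counted for each of them, so a promoter peak may belong to a neighbouring gene. Each list's percent open was placed among 10000 random lists of as many genes matched on the number of starts. Distal regions, more than 1 kb from any start, were counted within 50 kb of a gene's starts, and list medians were placed among 10000 random lists matched on the number of genes within 500 kb. In each percentile, random lists tied with the list were split evenly between above and below it. Percentiles describe these libraries and are not p-values.

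Motifs were 24 consensus sequences searched on both strands in 150 bp windows at the centres of distal peaks and in flanking windows centred 1 kb to each side, and in footprints extended by 3 bp against the same intervals shifted by 100 bp in a seeded random direction. Odds ratios had 0.5 added to each cell, tests were Fisher's exact tests of both tails per library, and p-values were adjusted by Benjamini and Hochberg over the 24 motifs. A motif was called where the adjusted p was under 0.05 in both libraries in the same direction. Consensus matches in shared promoter regions of the first 4 lists were set against the footprints of each library.

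The text names, for each list, up to 5 genes with the highest mean promoter height and up to 5 without a promoter peak in either library in list order. Cyp11a1, Star, Cyp11b1, Cyp11b2, Nr5a1, Mc2r, Th, Dbh, Pnmt and Chga are named in every case. It also names the 5 highest shared distal regions, the 10 genes with the most distal regions, the 3 highest peaks of each library without overlap in the other, and every motif. Some results that this rule would name are not reported here. Genes named outside it were chosen after their values were seen. Gene lists, motifs, tests, this rule and most of the alternative settings were fixed before the data were examined.

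For the closing section, the log2 height ratio of each shared region was centred on the median of regions in the same of 10 bins of GC content and 10 bins of height, apart for promoter and distal regions. It was then averaged over the regions within 50 kb of each gene's starts, and lists were placed among 10000 random lists matched on the number of such regions. This was repeated with genes of a list that share a region joined into 1 locus, and with each locus left out. A second adipocyte list (Cidec, Pnpla2, Slc2a4, Cebpa, Plin4, Aqp7, Gpd1, Adrb3, Fasn, Acaca, Dgat2, Cd36, Scd1 and Acvr1c) and a second endothelial list (Esam, Cldn5, Ramp2, Rasip1, Clec14a, Ptprb, Mmrn2, Sox7, Nos3, Icam2, S1pr1, Ecscr, Tspan18 and Fli1) were written for this, with 14 genes each and none on the first lists.

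On simulated data, 0 of 40 random lists of 20 genes fell outside the central 95%, and 39 of 40 lists with planted openness were found. Planted lists had 95% of genes open against 60% of all genes, and weaker differences were not simulated. Openness was drawn without regard to starts or CpG, so these runs cannot show whether the matching removes such effects. None of the 24 motifs was called with nothing planted, a CTCF site planted in 5% of 20000 windows was found in 5.00%, and a planted overlap of 60.3% of 20000 peaks was measured as 60.4%. The simulated windows held random bases, so they cannot show effects of base composition on motif calls. Alternatives covered stricter peaks, the other deposited list, the required overlap, promoter and distance windows, gene 5' ends, matching on CpG, motif windows and backgrounds, FDR thresholds and leaving out each library. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.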

Results

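DNase-seq marks open chromatin by where the enzyme DNase I cuts DNA in nuclei. It was run on adrenal gland, the organ whose cortex makes steroid hormones and whose medulla makes catecholamines. The animals were male adult B6CASTF1/J mice, an F1 hybrid strain, aged 18 to 20 months, and the 2 libraries formed 1 group, labelled biological replicates 1 and 2. The design therefore held no comparison between conditions, and the only comparison it implied was between the replicates, which asks how far the accessible regions of this tissue recur in a second sample. Peak heights were whole multiples of 1 step per library, 0.00531 in replicate 1 and 0.00750 in replicate 2. If heights are CPM, these correspond to 188.3 and 133.3 M cuts.

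Most genes of steroid hormone synthesis and all genes of the cholesterol list were open near a start in both libraries. Of 22 genes of adrenal steroidogenesis, 18 (81.8%) had a peak in both libraries within 1 kb of an annotated start. All 16 genes of cholesterol synthesis and uptake had one. Across 21805 protein-coding genes, 14073 (64.5%) did. Among 10000 random lists matched on the number of starts, steroidogenesis lay at percentile 98.2 and cholesterol at percentile 99.9. The steroidogenesis share of 81.8% equalled the upper limit of the central 95%, so its place rests on how ties were counted. Steroidogenesis lay inside the central 95% without replicate 1 (percentile 96.4), with gene 5' ends (91.4), with peaks above the median height (95.8) and with the shorter peak list (94.1). With random lists matched on promoter CpG content instead, steroidogenesis lay at percentile 100 and cholesterol at percentile 80.8, inside the central 95%.

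The highest steroidogenic promoter peaks were at genes for cholesterol supply, electron transfer and cAMP signalling. Npc1, which exports cholesterol from lysosomes, had a height of 9.06 ± 0.263 (SD, n = 2) at chromosome 18, 12236381 to 12236620. Lipe, the hormone-sensitive lipase that frees stored cholesterol, stood at 6.99 ± 0.513. Fdxr, the reductase that feeds electrons to mitochondrial P450 enzymes, stood at 6.55 ± 0.660, Scarb1, the receptor for high-density lipoprotein, at 6.16 ± 1.37, and Prkar2b, a regulatory subunit of protein kinase A, at 5.68 ± 0.762. For scale, the median over all genes open in both libraries was 3.90.

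Cyp11a1, Star, Nr5a1, Cyp11b1 and Cyp11b2 had peaks below that median. At Cyp11a1, which cleaves the cholesterol side chain in the first step of steroid synthesis, the peak spanned 58014901 to 58015100 on chromosome 9, inside an exon of the gene model. Its height was 3.09 in replicate 1 and 2.16 in replicate 2 (2.62 ± 0.658), from 582 and 288 cuts. Star, which moves cholesterol into mitochondria, had 1.94 ± 0.177 at 25806201 to 25806580 on chromosome 8. Nr5a1, which encodes the transcription factor SF-1, had 1.98 ± 0.197 at 38714401 to 38714600 on chromosome 2. Cyp11b1, the enzyme that completes corticosterone, had 1.37 ± 0.249 on chromosome 15, at 74841681 to 74841880. Cyp11b2, the aldosterone synthase of the outermost cortical zone, had 0.212 ± 0.0454, from 46 and 24 cuts, at 74856701 to 74857040 on the same chromosome.

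No promoter peak was listed in either library for Cyp21a1, Hsd3b1 or Mc2r. Cyp21a1 and Hsd3b1 encode further enzymes of the pathway, and Mc2r encodes the receptor for the pituitary hormone ACTH. The nearest peaks to a start of Mc2r lay 1284 bp away in replicate 1 and 1180 bp away in replicate 2. Nr0b1, a nuclear receptor that restrains SF-1, had a peak only in replicate 1, of height 0.207. It was named after its values were seen.

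**Figure D1:**
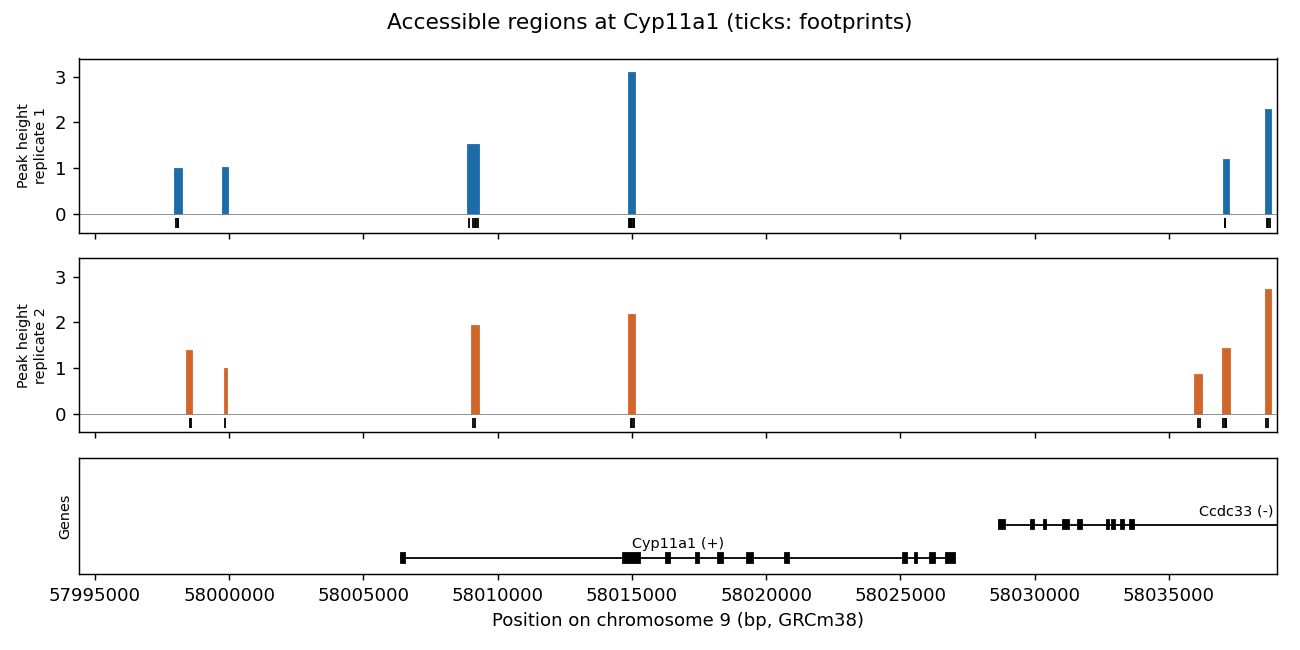
Deposited peaks and footprints around Cyp11a1 on chromosome 9, GRCm38; bars give peak height in each library, ticks give footprints, and the lowest panel gives exons and gene bodies with their strand. Replicate 1 had 6 peaks and 19 footprints in the window and replicate 2 had 7 and 16, and the peak over the exon stood at 3.09 and 2.16.

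Within the cholesterol list the highest peaks were at Insig1 (9.05 ± 0.862), a sensor protein of the sterol response, at Dhcr7 (8.43 ± 0.545), which catalyses the last step of cholesterol synthesis, and at Fdft1 (7.67 ± 0.391), the squalene synthase. Srebf2, the transcription factor that drives the pathway, stood at 6.57 ± 0.0733. Matches to the NFY consensus lay under a footprint in both libraries at 7 of the 16 genes, among them Fdft1, Hmgcs1, Idi1, Lss and Srebf2. Such NFY sites also lay at 2 steroidogenesis genes (Fdxr and Tspo), 2 zonation genes (Axin2 and Znrf3) and 1 chromaffin gene (Gata2). Whether an NFY match lay under a footprint more often in the cholesterol list than in these lists was not tested. The genes with such sites were named after their values were seen. An example on the plus strand was CGATTGG at chromosome 15, 82147132 to 82147138, 49 bp upstream of Srebf2. A footprint over an NR5A1 consensus was found in both libraries only at Hmgcs1, with TGGCCTTGG at chromosome 13, 119691419 to 119691427. For the steroidogenesis list, NR5A1 consensus matches in shared promoter regions lay at Gata6, under a footprint only in replicate 2, and at Inha, under none.

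Regulators of cortical zonation and capsule signalling were open in both libraries at 10 of 12 genes (83.3%), at percentile 87.2 with matching on starts and 49.7 with matching on CpG. Znrf3, a membrane ubiquitin ligase that dampens WNT signalling, had the highest peak (7.44 ± 0.407), followed by the WNT target Axin2 (4.32 ± 0.612). The hedgehog pathway genes Gli1 (4.14 ± 0.0864) and Ptch1 (2.89 ± 0.123) came next, and then Dab2 (2.13 ± 0.192), which marks the outermost zone. Shh, the hedgehog ligand itself, had no promoter peak listed in either library. A TCF/LEF consensus at Axin2, GCTTTGATG on chromosome 11, 108921231 to 108921239, lay under a footprint in both libraries.

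Chromaffin cell genes, which mark the medulla, were open in both libraries at 16 of 22 genes (72.7%), at percentile 91.5 with matching on starts and 9.70 with matching on CpG, both inside the central 95%. Without replicate 2 they lay above it (81.8%, percentile 98.2), as they did within 5 kb of a start (86.4%, percentile 98.6). Slc18a1, the vesicular monoamine transporter of chromaffin granules, had the highest peak at 12.5 in replicate 1 and 9.25 in replicate 2 (10.9 ± 2.29), rank 111 among all genes open in both libraries. Whether that peak serves Slc18a1 or a neighbouring gene was not tested. Chgb, a granule protein, stood at 3.74 ± 0.0469, and the transcription factor genes Gata3 and Gata2 stood at 3.53 ± 0.260 and 3.47 ± 1.27. The synaptic fusion gene Snap25 stood at 3.37 ± 0.240 and Chga, which encodes chromogranin A, at 1.79 ± 0.256. Th and Ddc, the genes for the enzymes that make dopamine from tyrosine, and Pnmt, whose product makes adrenaline, had no promoter peak listed in either library. The nearest peak to a Th start lay 5054 bp away in both libraries. Dbh, whose enzyme makes noradrenaline, had one only in replicate 1 (0.515). So did Phox2a (0.855), a regulator of noradrenergic identity named after its values were seen.

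Immediate early and clock genes were open in both libraries at all 14 and all 13 members measured, at percentiles 99.9 and 99.7 with matching on starts and 66.4 and 90.6 with matching on CpG. The highest immediate early peaks were at Jund (11.5 ± 1.00), Atf3 (8.91 ± 0.834), Egr1 (8.72 ± 0.629), Jun (8.42 ± 1.55) and Junb (8.11 ± 1.20). Among clock genes Tef (9.36 ± 0.867), Nr1d1 (8.67 ± 0.647), Per3 (8.57 ± 0.803), Per1 (8.06 ± 0.264) and Cry1 (7.60 ± 0.471) led. All 14 housekeeping controls were open, with Rplp0 highest (10.3 ± 0.875), then Actb, Polr2a, Ppia and Ywhaz, at percentiles 99.7 and 74.7.

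Lists for other cell types of the gland were open to differing degrees. This does not measure how much of each cell type was present, since 50% of skeletal muscle and 50% of forebrain control genes were also open. Adipocyte genes were open at 8 of 10 (80.0%), led by Plin1 (2.61 ± 0.0820), Cidea, Pparg, Fabp4 and Lep, with none for Cfd. Endothelial genes were open at 11 of 14 (78.6%), with the receptor genes Kdr (1.94 ± 0.450) and Flt1 (1.89 ± 0.251) highest, then Egfl7, Sox18 and Eng. Fibroblast genes were open at 9 of 12, with Col1a1 at 4.90 ± 0.258, then Pdgfra, Myh11, Nr2f2 and Pdgfrb, and none for Acta2. Schwann cell genes were open at 5 of 8 (62.5%), among them Pmp22, Erbb3, Mbp and Foxd3, with no peak in either library for Sox10. With matching on starts these 4 lists lay at percentiles 89.3, 69.8, 68.1 and 41.8. With matching on CpG they lay at percentiles 99.96, 97.4, 99.2 and 51.4, the first and the third above the central 95%. In the shorter list and among peaks above the median height, open adipocyte genes numbered 5 of 10 both times and endothelial genes 7 and 6 of 14. Fibroblast genes then numbered 3 and 4 of 12, at percentiles 0.195 and 1.90, below the central 95%.

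Blood cell lists other than erythroid genes changed place with the way of matching. Of the macrophage genes 7 of 14 were open, at percentile 7.58 with matching on starts but 99.3 with matching on CpG, and 21.4% were open in the shorter list and 35.7% among peaks above the median height, at percentiles 0.045 and 2.40. Spi1, the myeloid regulator PU.1, led with 1.06 ± 0.00845, then Fcer1g, Cd14, Cd74 and Cd68, while Ptprc, Csf1r, C1qa, C1qb and Tyrobp had no promoter peak. Lymphocyte genes were open at 3 of 12 (25.0%), namely Pax5 (3.34 ± 0.306), Ikzf1 and Ikzf3, at percentiles 0.440 and 8.33, and the receptor genes Cd3e, Cd3g, Cd79a and Cd79b had none. Erythroid genes were open at 3 of 8 (37.5%), Epor and Tal1 among them, at percentile 8.98 with matching on starts and inside the central 95% with both, with none for Klf1, Alas2, Gata1, Hbb-bt and Hbb-bs.

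Among genes of other organs, chosen as controls, those of hepatocytes and kidney were mostly without promoter peaks. Only 2 of 14 hepatocyte genes (14.3%) were open, Apoh (5.03 ± 0.732) and Pck1 (1.52 ± 0.780), and Alb, Ttr, Serpina1a, Ahsg and Fgb had none. For kidney epithelium 2 of 12 (16.7%) were open, Pax2 (0.557 ± 0.0819) and the proximal tubule gene Lrp2, and Slc12a1, Umod, Nphs1 and Slc34a1 had none. Open genes numbered 3 of 11 for pancreas (27.3%; Nkx6-1, Ins2 and Neurog3), 3 of 10 for testis germ cells (Dazl, Zpbp and Spata3), 6 of 12 for forebrain neurons (Grin1, Dlx1, Bdnf, Gad1 and Emx1 highest) and 5 of 10 for skeletal muscle (Actn3, Cacna1s, Ckm, Tnnt3 and Myl1). Percentiles with matching on starts were 0.01 for hepatocytes, 0.0300 for kidney, 2.42 for pancreas, 1.53 for testis, 11.9 for neurons and 17.2 for muscle. With matching on CpG they were 5.12, 0.0900, 1.00, 0.440, 1.02 and 87.0 in the same order. Without replicate 2, 45.5% of pancreas genes, 6 of 10 testis genes and 9 of 12 neuron genes were open, with pancreas at percentile 17.8 and testis at 33.7. Without replicate 1 these 2 lists lay at percentiles 5.69 and 4.12, so with either library alone they were inside the central 95%. In the shorter list and among peaks above the median height, open muscle genes numbered 1 and 3 of 10 (percentiles 0.04 and 3.38), neuron genes 4 of 12 both times (2.06 and 2.80) and kidney genes 0. Only 10 of the 20 lists kept their side of the central 95% between the 2 ways of matching.

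**Figure D2:**
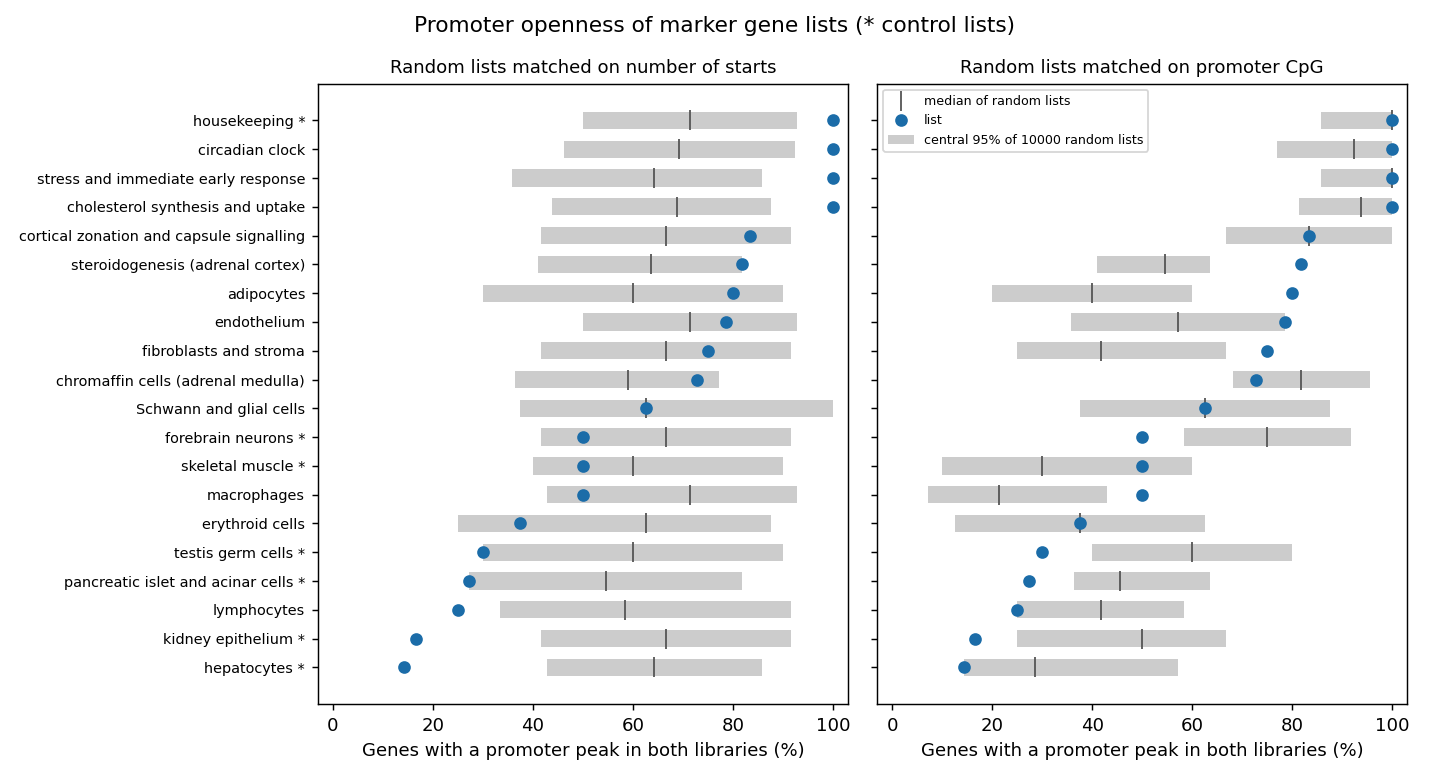
Percent of each list's genes with a promoter peak in both libraries (points) against the median and the central 95% of 10000 random lists, matched on the number of starts in the left panel and on promoter CpG content in the right panel; asterisks mark control lists. Steroidogenesis (81.8%) lay above the grey range with matching on CpG and at its upper edge with matching on starts, and kidney (16.7%) lay below it in both panels.

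Regions away from starts were counted within 50 kb of each gene's starts. The median immediate early gene had 9.5 distal regions shared by both libraries, the median clock gene 6 and the median housekeeping gene 5.5, against 2 over all genes. Macrophage genes had a median of 5 and endothelial genes 4.5. Percentiles among random lists matched on gene density were 100, 99.9, 99.7, 98.5 and 98.7, so 5 of the 20 lists lay above the central 95% and none lay below it. Without replicate 1 only immediate early and clock genes (median 11) did, with housekeeping genes at percentile 94.6, macrophages at 88.1 and endothelium (median 7) at 96.0. Without replicate 2 macrophages (85.2) and endothelium (96.1) lay inside the range, while steroidogenesis (median 9.5, percentile 100) and Schwann cells (99.2) lay above it. Macrophages were also inside it within 100 kb (92.6), within 20 kb (87.0) and in the shorter list (96.4). Endothelium was inside it in the shorter list (median 2.5, percentile 95.5) and among peaks above the median height (2, 84.5), where forebrain neurons, a control, lay above it (99.0 and 98.8). With both libraries and 50 kb, steroidogenesis had a median of 3.5 (percentile 93.9), zonation 3.5 (95.1) and chromaffin genes 3 (88.3), all inside that range, but steroidogenesis lay above it within 100 kb (99.8) and zonation within 20 kb (98.3). B4galt5 had the most distal regions, 44, and others with many were Ptgis and Tns1 with 28, Cptp, Ints11, Tas1r3, Tmem107 and Vamp2 with 27, and Ube2j2 with 26. Neighbouring genes counted the same regions, as Cptp, Ints11, Tas1r3 and Ube2j2 did on chromosome 4 and Tmem107 and Vamp2 on chromosome 11.

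The highest distal peak, 75.8 ± 5.15 (SD, n = 2), lay at chromosome 17, 39846781 to 39846900, over the ribosomal RNA gene CT010467.1. Next came 57.3 ± 1.03 at chromosome 9, 123461921 to 123462080, in an exon of Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, with Limd1 as the nearest start. A peak of 49.8 ± 2.21 lay between genes at chromosome 6, 49236441 to 49236620, with Igf2bp3 as the nearest gene. The remaining named peaks lay in introns of Kpna1 (49.6 ± 6.55, chromosome 16, 35981661 to 35981840) and Il31ra (41.8 ± 1.32, chromosome 13, 112578161 to 112578320). For scale, the 90th percentile of promoter heights over genes open in both libraries was 7.59. Copy number and read mappability at these 5 sites were not examined, so their heights need not measure accessibility.

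Among consensus sequences in distal peaks, those of CTCF and NFI were the most enriched against flanks, an order that changed with the background below CTCF. The CTCF site, bound by the protein that anchors chromatin loops, had a log2 odds ratio of 5.49 in replicate 1 and 5.63 in replicate 2 against flanks 1 kb away, and 7.40% and 6.82% of windows held it. NFI followed with 4.09 ± 0.47 (SD, n = 2), then CEBP with 2.52 ± 0.85, NRF1 with 1.99 ± 0.42, the cAMP response element with 1.84 ± 0.22, AP-1 with 1.59 ± 0.35 and RFX with 1.57 ± 0.28. The glucocorticoid receptor site had 1.25 ± 0.10 and SP/KLF 1.14 ± 0.11. The NR5A1 (SF-1) site had 0.68 ± 0.04 (SE) in replicate 1 and 1.05 ± 0.04 in replicate 2, present in 2084 of 69562 and 3133 of 87470 distal windows against 2624 of 139124 and 3077 of 174940 flanks. Its adjusted p by Fisher's exact test was 3.11e-55 and 3.59e-173, for both tails and over 24 motifs, which measures counting error within each library. In promoter peaks the same site was below its flanks, at -0.60, and AP-1 (0.0067) and NFI (1.95) were not called in both libraries. Against dinucleotide-shuffled windows CTCF (5.96) was followed, among called motifs, by RFX (3.90), NRF1 (3.51), the cAMP response element (2.62) and SP/KLF (2.58), NFI fell to 2.26, NR5A1 rose to 1.55, above AP-1 (1.35), and CEBP fell to 0.93 and was no longer called. Among peaks above the median height 4 motifs lost their call, RFX (1.21) among them.

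Smaller enrichments in distal peaks were seen for ETS (0.81 ± 0.07), PU.1 (0.44 ± 0.10), TEAD (0.27 ± 0.07) and NFY (0.11 ± 0.00217). NFY was depleted against shuffled windows (-0.55), and TEAD was depleted in promoter peaks (-0.41). ETS was not called in both libraries against shuffled windows (1.07), and neither ETS (0.82 and 0.84) nor TEAD (0.22 and 0.19) was called among peaks above the median height or in the shorter list. In all, 15 of 24 motifs were enriched in both libraries, 2 were depleted in both and 7 were neither. The depleted motifs were GATA (-0.43 ± 0.06) and PHOX2 (-2.07 ± 0.40), the latter a site of the noradrenergic regulators, and both turned above 0 against shuffled windows (0.25 and 0.73, the latter not called). Motifs without a shared call were DR1 (0.54 ± 1.26), HNF4 (0.19 ± 0.12), SOX (-0.01 ± 0.01), TCF/LEF (-0.02 ± 0.05), RUNX (-0.06 ± 0.13), MEF2 (-0.08 ± 0.52) and HNF1 (-1.58 ± 0.05). Taken alone, replicate 2 had calls above 0 for DR1 (1.43), HNF4 (0.27) and MEF2 (0.29), and replicate 1 had calls below 0 for RUNX (-0.16), MEF2 (-0.44) and HNF1 (-1.62).

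Replicate 2 had 1.20 times as many footprints, the short protected stretches within open chromatin, as replicate 1: 273271 against 228557 (250914 ± 31618, SD, n = 2). Footprints repeated much of the motif order. CTCF had 4.83 ± 0.23, NFI 3.45 ± 0.28, CEBP 2.06 ± 0.45, RFX 1.69 ± 0.32, NRF1 1.67 ± 0.12 and the cAMP response element 1.59 ± 0.15 against intervals shifted by 100 bp. SP/KLF had 1.27 ± 0.04, AP-1 1.15 ± 0.52, ETS 0.90 ± 0.10, NR5A1 0.82 ± 0.20 and NFY 0.31 ± 0.06. In all, 12 motifs were enriched in both libraries, and SOX (-0.17 ± 0.01), RUNX (-0.21 ± 0.05), GATA (-0.76 ± 0.13) and PHOX2 (-2.24 ± 0.92) were depleted in both. The 8 others were neither: glucocorticoid receptor (0.49 ± 0.22), MEF2 (0.23 ± 0.44), HNF4 (0.21 ± 0.26), DR1 (0.04 ± 1.78), TEAD (0.02 ± 0.16), TCF/LEF (-0.13 ± 0.04), PU.1 (-0.17 ± 0.02) and HNF1 (-0.99 ± 0.20). Replicate 2 alone had calls for the glucocorticoid receptor (0.64), MEF2 (0.54), TEAD (0.14) and PU.1 (-0.19). Outside promoters ETS (0.93), NFY (0.11), RUNX (-0.10) and PHOX2 (-1.97) were not called in both libraries, nor were ETS (0.51), RUNX (-0.019) and PHOX2 (-1.02) with a shift of 50 bp. Of the footprints 88.9% and 90.6% lay in peaks, and 75.8% and 78.1% of peaks held at least 1.

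**Figure D3:**
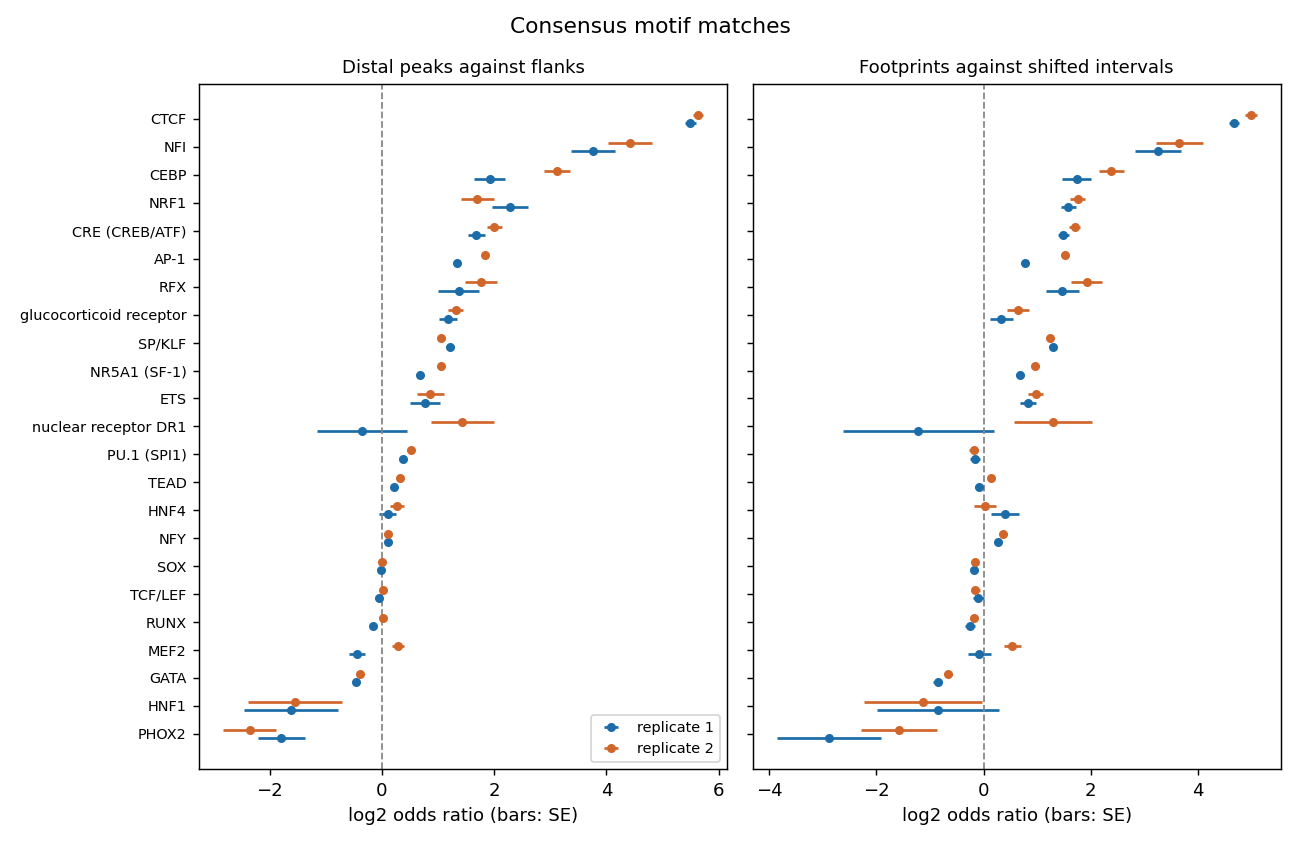
log2 odds ratio of consensus sequences in distal peaks against flanks (left) and in footprints against shifted intervals (right), 1 point per library with its SE as a bar. CTCF stood highest in both panels, at 5.49 and 5.63 in peaks, and PHOX2 lay below 0 in both libraries.

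Between the replicates, tall peaks recurred more often than short ones. Replicate 1 had 98630 peaks and replicate 2 had 118249 (108439.5 ± 13873, SD, n = 2), a ratio of 1.20. The step in height was 1.41 times larger in replicate 2, so the library with the larger step had more peaks. Of the peaks of replicate 1, 69.8% (exact binomial 95% interval 69.5 to 70.1) overlapped a peak of replicate 2, and 58.1% (57.9 to 58.4) the other way, against 1.86% and 1.54% for peaks placed at random. In the 10% of peaks with the greatest height 99.7% and 99.6% were shared, and in the lowest 10% of peaks 1.66% and 12.5%. The median height was 1.06 and 1.27 for shared peaks and 0.276 and 0.457 for those of a single library.

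Promoters were over-represented among peaks, and less so among those of a single library. Promoter peaks made up 28.6% (28.3 to 28.9) and 25.2% (24.9 to 25.4) of the libraries (26.9 ± 2.42, SD, n = 2), against 2.47% of random positions. Among peaks of a single library they made up 14.2% and 11.8%. Introns held 30.7% and 33.5%, exons 5.38% and 3.99%, and intergenic sequence 35.3% and 37.4%. Merging both libraries gave 142626 regions, of which 65385 held a peak of each, 22421 near starts and 42964 distal. The Y chromosome, present in these male animals, had 132 and 81 peaks, and the X chromosome had 0.390 ± 0.0138 times the autosomal density of peaks. Positions listed at an FDR of 0.05 covered 1.14% and 1.37% of the genome (1.25 ± 0.160).

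Heights in shared regions correlated across regions, which are not independent replicates, with Pearson r 0.934 on the log2 scale and Spearman rho 0.922. The coefficient was 0.962 near starts and 0.900 in distal regions. The median log2 ratio of replicate 2 to replicate 1 was 0.12 (SD across regions 0.46), and 94.8% of regions lay within 2-fold. This ratio fell with the GC content of the region (Pearson r -0.454). Regions around adipocyte genes were higher in replicate 2, and those around endothelial genes lower, by a mean log2 of 0.23 and -0.25 after matching on GC content and height (0.35 and -0.18 without matching). Those around steroidogenic genes were lower only after matching (a mean of -0.00142 over genes without it), by -0.10 with genes that share regions counted as 1 locus (percentile 1.22 of random lists), but the list lay inside the central 95% without the locus of Hsd3b1 and Hsd3b6 (5.40) or that of Cyp11b1 and Cyp11b2 (3.91).

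**Figure D4:**
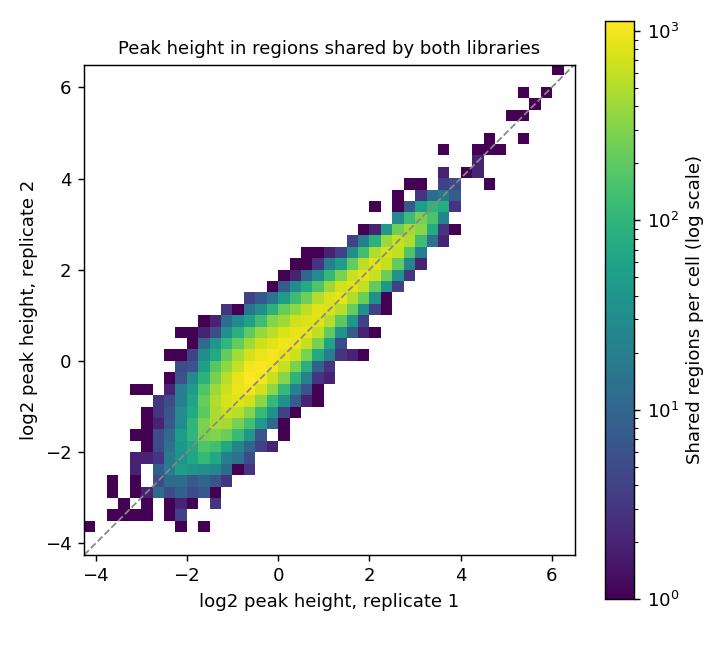
log2 peak height in replicate 1 (horizontal) and replicate 2 (vertical) for the 65385 shared regions, coloured by regions per cell on a log scale, with a dashed line of equal height. Points gather along the line with Pearson r 0.934 and spread more widely at low heights.

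Footprint calls recurred less than peaks. At least 1 bp was shared for 53.7% (53.5 to 53.9) of the footprints of replicate 1 and 44.8% (44.6 to 45.0) of those of replicate 2. For footprints inside peaks the shares were 55.8% and 45.8%, against 37.4% and 30.6% when footprints were moved at random within the peaks that held them.

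The highest peaks found in a single library lay near annotated starts and next to a peak of the other library. In replicate 1 they were at Stip1 (6.42), Hlcs (6.29) and Jun (5.95), and in replicate 2 at Rab8a (6.83), Ttc16 (5.86) and Mtrf1l (5.83). At each of the 6 the other library had a peak touching the site or 40 bp away. Its height was 6.25 beside the Stip1 peak and 10.4 beside the Rab8a peak.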

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

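The alternatives using FDR-listed positions, and those using the shorter peak list for promoter share, peak height, gene lists and distal motifs, were chosen only after the data were seen; the others were planned, and the causes of the changes were not tested except where fewer peaks follow from the setting. The number of accessible regions per library averaged 54013.5 with peaks above the median height, 67462.5 in the shorter list and 98630 to 118249 with 1 library left out. The share of peaks shared between replicates was 52.6% with a reciprocal overlap of 50% and 83.9% for the 49315 highest peaks of each library, and the share of footprints shared between replicates 36.8% with an overlap of 50%. The correlation of peak height between replicates was 0.922 by ranks, 0.906 in regions above the median height and 0.900 in distal regions. The share of peaks at promoters was 20.4% within 500 bp, 32.2% within 2 kb, 21.6% with gene 5' ends, 39.8% above the median height and 34.6% in the shorter list. FDR-listed positions covered 0.999% of the genome at 0.01 and 0.792% at 0.001. The X ratio was 0.367 in the shorter list and 0.248 above the median height. Steroidogenesis genes were open at 86.4% within 5 kb, 72.7% with 5' ends, above the median height or with the shorter list, and 81.8% to 86.4% with 1 library left out, and chromaffin genes at 86.4%, 63.6%, 45.5% and 63.6%, and 77.3% to 81.8%. Lists above the central 95% for distal regions numbered 3 within 20 kb (immediate early, endothelial and zonation genes) and 2 to 5 with 1 library left out (2 without replicate 1), against 5, and their members changed. Median distal regions were 8.5 within 100 kb, 1 within 20 kb and 6 to 9.5 with 1 library left out for steroidogenesis, and 5, 1, 4 to 6, and 1.5 in the shorter list, for chromaffin genes. Matching on CpG left 10 of 20 lists on the same side of the central 95% for openness, the shorter list 14 and the other settings 16 to 19. In the shorter list macrophage, fibroblast, muscle and neuron genes fell below the central 95%, as macrophages and fibroblasts did above the median height and neurons with 5' ends. Testis genes lay inside it with the shorter list, above the median height and with FDR-listed positions. Of the distal motifs, NR5A1 turned to -0.60, TEAD to -0.41 and HNF4 to -0.54 in promoter peaks. Against dinucleotide-shuffled windows the turns were GATA 0.25, HNF1 0.85, MEF2 1.68, NFY -0.55, PHOX2 0.73, RUNX 0.71 and SOX 0.030. MEF2 turned to 0.063 and DR1 to -0.25 in the shorter list, and MEF2 to 0.12 above the median height. With 1 library left out, values ranged from -0.44 to 0.29 for MEF2, -0.16 to 0.028 for RUNX, -0.015 to 0.00161 for SOX, -0.056 to 0.017 for TCF/LEF and -0.35 to 1.43 for DR1. In footprints, HNF1 turned to 0.74 and MEF2 to -0.15 outside promoters, TEAD to -0.0083 with a shift of 50 bp, and with 1 library left out MEF2 ranged from -0.080 to 0.54, TEAD from -0.093 to 0.14 and DR1 from -1.22 to 1.30. CTCF, NRF1, SP/KLF, PU.1 and the cAMP response element were called enriched in peaks under every setting run, and NFI, AP-1, NR5A1 and the glucocorticoid receptor site under all but promoter peaks. The planned restriction to footprints of better score, for 3 results, was not run because the score did not vary. No paired analysis was possible because there was 1 group. A motif with few matches, such as DR1 with 4 and 15 distal windows, is limited by counts.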

Other observations

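The tests of GC content were chosen only after the result was seen, both for the trend itself and for the gene lists, as were those with shared loci counted once or left out; the tests with second lists and of high peaks in a single library were set before theirs.

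Genes of fat and vessels differed between the 2 libraries. Around adipocyte genes, shared regions averaged 0.23 ± 0.08 (SE over genes) higher on the log2 scale in replicate 2 after matching on GC content and height, with 9 of 10 genes higher, among them Pparg (0.64), the master regulator of fat cells, Lep (0.45) and Cidea (0.33), and Adipoq lower (-0.24) although its promoter peak was listed only in replicate 2. Endothelial genes were lower in replicate 2 by a mean of -0.25 ± 0.06, in 13 of 14 genes, with Tie1 (-0.63), Cdh5 (-0.54) and Kdr (-0.51) lowest, and Pecam1 higher (0.13) although its promoter peak was listed only in replicate 1. The steroidogenic list averaged -0.00142 without matching, -0.15 over genes with it (percentile 0.0900) and -0.10 ± 0.06 over 19 loci when genes sharing regions counted once (percentile 1.22), but lay inside the central 95% without the locus of Hsd3b1 and Hsd3b6 (-0.79, percentile 5.40) or that of Cyp11b1 and Cyp11b2 (percentile 3.91), while the adipocyte and endothelial lists stayed outside whichever locus was left out, and the 17 remaining lists lay inside with all loci. Distal regions with a CEBP site, a family active in adipocytes, averaged 0.40 ± 0.05 (SE, 76 regions) higher in replicate 2. Those with NR5A1 sites averaged -0.015 ± 0.011, a smaller shift than that of the steroidogenic list. Those with ETS sites (-0.044 ± 0.061, 37 regions) were too few to tell whether they followed the endothelial list. Sites of other motifs shifted too, among them NRF1 (-0.22 ± 0.05), NFI (-0.20 ± 0.05), the glucocorticoid receptor (-0.09 ± 0.04), GATA (-0.05 ± 0.01), HNF4 (0.15 ± 0.05) and TEAD (0.08 ± 0.01). Which cell types the motif shifts reflect was not tested.

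GC content or height of the listed regions is argued against as the whole source of these differences. Matching on both, in bins, left adipocyte genes at percentile 100 and endothelial genes at percentile 0 of random lists. A second adipocyte list was also higher in replicate 2, by 0.14 ± 0.06 in 12 of 14 genes (percentile 99.79; 0.25 without matching), and a second endothelial list lower after matching, by -0.12 ± 0.04 in 11 of 14 (percentile 0.36), but at -0.00485 without matching, where the median over all shared regions was 0.12. The second lists fell as predicted if the replicate 2 sample held more adipose tissue and the replicate 1 sample more endothelium, which stays a hypothesis. Heights were normalised for depth, so more endothelium in replicate 1 cannot be told from more of other cells in replicate 2. How such a difference might arise was not tested. With 1 group, no other biological explanation was tested, and a difference in the animals stays open.

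The ratio of replicate 2 to replicate 1 height fell with GC content, from a median log2 of 0.56 in regions of 30% to 40% GC to -0.36 in those of 80% to 100%. A difference in promoter accessibility between the samples is argued against as the whole source by the same fall in distal regions (r -0.333). A GC bias between the libraries is a candidate source, since the trend was present in promoter regions (r -0.507), distal regions and on the X chromosome (r -0.434). Peaks of a single library averaged 54.5% GC in replicate 1 and 50.8% in replicate 2. No other biological explanation was tested.

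Among the 100 highest peaks of each library without overlap in the other, 91% and 83% lay near starts. Chromatin closed both at these sites and around them in the other library is argued against, because that library listed a position at an FDR of 0.05 in 100% and 97% of them. It had a peak within 150 bp in 94% and 89%, which fits a peak placed beside the site. It listed a position at 0.001 or less in 100% and 96%, as predicted if a caller or later filter left out an open site. With a peak so near, the listed positions may be its edge, so they cannot tell a left-out site from a displaced peak. Nor can they show that the site itself was open. Both may hold for different sites. Over all peaks of a single library, only 11.1% and 9.67% held an FDR-listed position of the other library, so most of the remaining low peaks were not listed there at all.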
